A study of Mus musculus with 2 samples.

How the data were processed

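Single-cell RNA libraries of lymph node immune cells were measured in 2 groups, 1 library each: recipients of an allogeneic heart graft and recipients of a syngeneic heart graft. Libraries were made with a Chromium single-cell 3′ kit, per the labels' protocols. The authors deposited for each library a matrix of raw UMI counts per gene and cell barcode, with values that are whole numbers and were not normalised. Cell Ranger 2.2.0, STAR, Seurat 2.3.4 and the mm10 build are named in the submitters' processing notes, with no role or order. How the barcodes were selected before deposit, and whether the reads of both libraries were trimmed and mapped alike, is not given in the sources used here, and the barcode lists start at different UMI numbers, 150 in the allogeneic library and 3447 in the syngeneic library. The gene list has 27998 entries with 27933 symbols, of which 56 stand for several entries, whose counts were summed. The libraries held 8415043 UMIs (allogeneic) and 46486632 UMIs (syngeneic), so the floor of 3 UMIs corresponds to 0.357 and 0.0645 CPM of the whole libraries.

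Barcodes were kept with at least 200 genes and at most 10% mitochondrial UMIs, and doublets were called per library with Scrublet as built into scanpy 1.11.5. In the allogeneic library 1071 barcodes had fewer genes and 622 more mitochondrial UMIs. The caller marked 15 of 2106 allogeneic cells and 0 of 7957 syngeneic cells, so no doublets were taken out of the syngeneic library here, and whether any were taken out before deposit is not given in the sources used here. Counts were scaled to equal totals, log-transformed and reduced to 30 principal components of 2000 variable genes chosen per library. Both libraries were clustered together without integration, and T cells were then clustered again alone. The graph joined cells by shared members of their 15 nearest neighbours, and Leiden clustering (leidenalg 0.10.2) at resolution 1 kept the best of 10 random starts. A first graph gave a syngeneic regulatory T cluster at some random starts and none at others, so this graph and the numeric rule for names were chosen after seeing the data. The cell filter, the marker lists, the gene lists, the rule for named genes and the planned comparisons were set before the data were examined.

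Clusters were named from the marker lists by the mean marker level relative to the other clusters. A cluster stayed unnamed with fewer than 3 markers seen in at least 10% of its cells, with a further lineage at 0.8 of the best score, or with more markers of another class than of its own among its 10 leading genes. T cell subclusters were called CD4 or CD8 from the levels of Cd4, Cd8a and Cd8b1, taken as shares of the level in the second highest cluster. The share had to be at least 0.5 for the own gene and at most 0.15 for the other. Regulatory T needed a marker score of 0.7 and gamma-delta T a score of 0.8, each with 3 own markers seen in at least 10% of cells and with the score of the other below 0.8 of its own, and cycling T needed 5 cycling markers among the 10 leading genes. Subcluster T8 (44 allogeneic and 196 syngeneic cells) had a gamma-delta score of 1.0 and a regulatory T score of 0.830, so it got neither name and was left among T cells with no narrower name, and no other subcluster reached the gamma-delta score. Class shares have exact binomial (Clopper-Pearson) 95% intervals.

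UMIs were summed per library and class for classes with at least 100 cells in each library, and given as CPM of all UMIs of that class. The sums were 2179977 (allogeneic) and 11802725 (syngeneic) UMIs in CD4 T cells, 1787389 and 13560143 in CD8 T cells, 711993 and 2493320 in regulatory T cells, and 798216 and 4753694 in B cells. Ratios are allogeneic over syngeneic with exact Poisson 95% intervals. Cells are not replicates, so no p-value, standard error or number of changed genes was made from them. A ratio against 0 UMIs was computed against a floor of 3 UMIs over the class. The lower limit of its interval can lie below that value.

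Genes were named by a fixed rule of size: among genes with at least 50 UMIs over both libraries and 50 CPM in either, without mitochondrial, ribosomal protein and receptor segment genes, the 10 highest and 10 lowest ratios whose interval excluded 0. Up to 4 members of each list with the highest CPM and the strain and sex check genes were named too. Only part of these genes is described, and 1 of the genes the rule names is not reported here. Ly6e in CD8 T cells, Foxp3 and the genes Fkbp5, Tsc22d3, Klf9 and Txnip were chosen after their values were seen, as were the genes for shares of cells with a UMI. The 22 gene lists cover interferon-gamma and type I interferon responses, cytotoxic and effector genes, checkpoint receptors, T cell activation, naive lymphocytes, regulatory T, follicular helper T, proliferation, MHC class I and II, B cell activation and germinal centre, immunoglobulin constant, secretion and unfolded protein, immediate early, heat shock, p53 and apoptosis, glycolysis, oxidative phosphorylation, NF-kB and TNF, chemokines and cytokines, and nuclear RNA. Members with at least 20 UMIs over both libraries entered, a list's median log2 ratio was set among 10000 random lists of the same size matched on mean expression, and its counting interval came from 2000 redraws of the UMI counts.

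For shares of cells with a UMI, each cell was thinned to 1000 UMIs. Free RNA was estimated from 942 allogeneic barcodes under 200 genes whose UMIs were at most 50% haemoglobin, which held 184696 UMIs. Its share of a class was the class's haemoglobin share over the 4.83% of those barcodes: 8.15% in CD4 T, 9.95% in CD8 T, 8.37% in regulatory T and 9.75% in B cells. It was subtracted from the allogeneic sums only, since the syngeneic library has no barcodes under 200 genes. Alternatives were other cell filters, doublet treatments, Leiden resolutions, random starts, clustering of each library alone or after thinning, CPM without mitochondrial, ribosomal protein and immunoglobulin genes, median-of-ratios scaling, other UMI minimums for list members, reweighting of classes and other thinning depths. Cells of at least 3447 UMIs alone, removal of the 5% highest doublet scores, other random starts and subtraction of free RNA were added after seeing the data.

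The ratio and list steps were tested on simulated data drawn from the real class means, with 200 changed genes. The draws were Poisson sums from 1 profile per class, the same model that the intervals assume. They hold no variation between cells or libraries and no free RNA. The rates below thus check the computation and are not error rates of the real comparison. Intervals excluded 0 for 3.70% of unchanged genes in CD8 T cells (8743 genes) and 4.42% over all cells (11062 genes), with the other classes between. In B cells (7225 genes) 71% of 2-fold and 99% of 4-fold changes were recovered, and in CD4 T cells (8663 genes) 91% and 99%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9 were used.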

Results

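Immune cells from lymph nodes were compared between mice that had received an allogeneic heart graft, from a C57BL/6 donor into a BALB/c recipient, and mice that had received a syngeneic graft, from BALB/c into BALB/c. An allogeneic graft carries transplantation antigens that the recipient lacks, whereas a syngeneic graft is genetically matched to its recipient. Each group had 1 droplet-based single-cell RNA library, so no difference given here has a replicate check and none was tested. The number of mice behind each library is not given in the sources used here. Intervals are at 95% and cover counting error only. They are exact for shares and single genes, and come from redraws of the UMI counts for list medians. The allogeneic library held 3500 barcodes with 8415043 unique molecular identifiers (UMIs), and the syngeneic library held 7967 barcodes with 46486632 UMIs. The lowest barcode had 150 UMIs in the allogeneic library and 3447 in the syngeneic library, with medians of 1950.5 and 4917 UMIs. After the cell filter, 2091 allogeneic cells (59.7% of barcodes) and 7957 syngeneic cells (99.9%) were kept, with medians of 3135 and 4917 UMIs and of 1269 and 1665 genes. Haemoglobin genes took 9.0% of the UMIs of kept allogeneic cells and 0.114% of those of kept syngeneic cells.

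**Figure D1:**
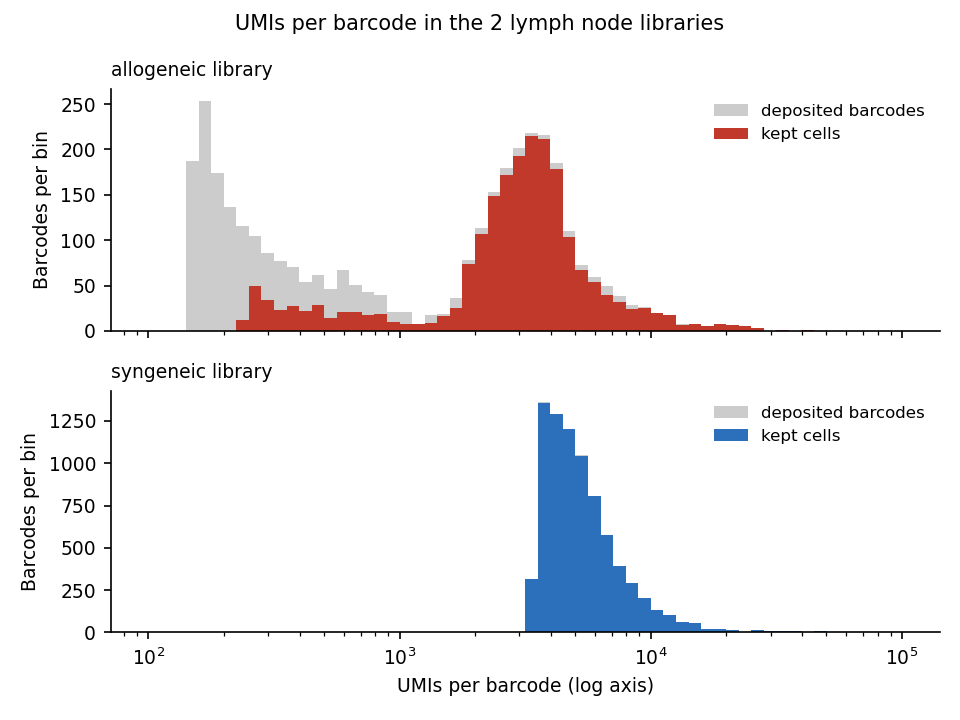
Number of barcodes by UMIs per barcode (log axis) in the allogeneic and syngeneic libraries, with all deposited barcodes in grey and kept cells in colour. The deposited barcodes start at 150 UMIs in the allogeneic library and at 3447 UMIs in the syngeneic library.

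The first comparison asked how the makeup of the lymph node differed between the graft types. CD8 T-like cells, the class that holds most cytotoxic lymphocytes, made up 19.0% (17.3 to 20.7%) of the allogeneic cells and 30.1% (29.1 to 31.1%) of the syngeneic cells. Germinal centre B-like cells, in which antibody genes mutate, made up 0.430% (0.197 to 0.815%) and 2.05% (1.75 to 2.38%), which is 2.70% and 14.3% of all B-like and germinal centre B-like cells. They made up 1.0% and 3.52% at Leiden resolution 0.5, and 0% and 2.01% with each library clustered alone. Regulatory T-like cells, which restrain other T cells, made up 10.6% (9.28 to 12.0%) and 5.54% (5.05 to 6.07%). Erythroid-like cells made up 3.30% of allogeneic and 0.0754% of syngeneic cells. CD4 T-like cells had closer shares of 31.0% (29.0 to 33.0%) and 32.0% (31.0 to 33.1%), and B-like cells had 15.5% (14 to 17.1%) and 12.3% (11.5 to 13%). Cycling T-like cells made up 0.574% (0.297 to 1.0%) of allogeneic and 1.47% (1.22 to 1.76%) of syngeneic cells. Natural killer-like cells were near each other at 0.478% and 0.628%, and myeloid-like cells, a mix of monocyte, dendritic and neutrophil clusters, stood at 2.2% and 0.880%. The neutrophil cluster held 22 allogeneic cells and 1 syngeneic cell, the dendritic cluster 9 and 53, and the monocyte cluster 15 and 16, and the allogeneic myeloid-like share was 6.55% at Leiden resolution 2, with each library clustered alone and at other random starts (set 3). Plasmacytoid dendritic-like cells, known as interferon producers, were 79 syngeneic cells (0.993%) and 0 of 2091 allogeneic cells, with an interval up to 0.176%. T cell clusters given no narrower name held 2.68% of allogeneic and 8.09% of syngeneic cells. Clusters left unnamed held 14.3% and 5.91%: a macrophage and erythroid mix with a median of 452 UMIs held 297 allogeneic and 25 syngeneic cells, and a mix of B and T cells held 2 and 445.

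These shares were taken across a gap in depth and from barcode lists with different UMI minimums. Among cells with at least 3447 UMIs alone, an alternative added after seeing the data, CD8 T-like cells made up 36.6% of allogeneic cells and 29.9% of syngeneic cells, so their order turned. Allogeneic B-like cells made up 0.231% there (2 cells), although 32 of the allogeneic cells named B-like in the main clustering reach that depth, and 31 allogeneic cells stayed unnamed, so this share reflects the naming of clusters too. The regulatory T-like share depended on the clustering: the syngeneic value was 0.591% with doublets kept and 2.85% with each library clustered alone, and at Leiden resolution 2 the shares were 0.430% and 0.691%. With a stricter filter of 500 genes and 5% mitochondrial UMIs the shares were 1.12% and 8.39% for regulatory T-like cells, and the allogeneic B-like share was 0.352%, while 31.2% of allogeneic and 5.90% of syngeneic cells stayed unnamed. After thinning to 1000 UMIs no cluster was named CD4 T, and CD8 T-like cells made up 0.949% and 27.0%, while 74.4% of allogeneic and 5.23% of syngeneic cells stayed unnamed. Under both settings the low allogeneic shares go with more cells left without a name and are not read as a loss of cells.

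**Figure D2:**
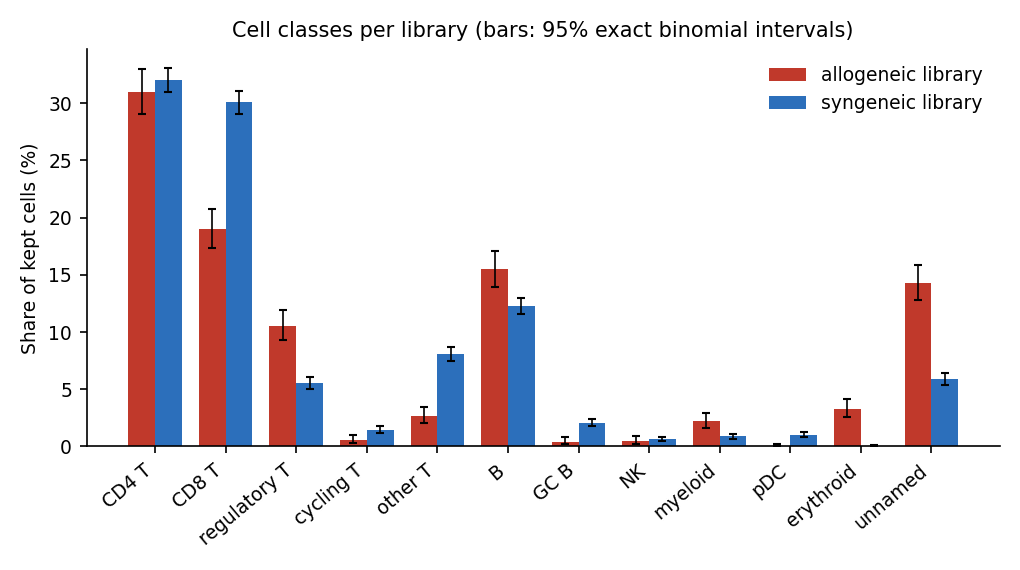
Share of kept cells (%) in each cell class of the allogeneic (2091 cells) and syngeneic (7957 cells) libraries, with exact 95% binomial intervals as error bars. CD8 T cells took 19.0% and 30.1%, and regulatory T cells 10.6% and 5.54%.

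Expression was then compared within 4 classes that had at least 100 cells in each library, called CD4 T, CD8 T, regulatory T and B cells from here on. Each library's cells lay almost wholly in clusters of its own. CD4 T cells were subcluster T3 in the allogeneic library and T0 (74.7%) and T4 (25.3%) in the syngeneic library. CD8 T cells were subcluster T6 in the allogeneic library and T1, T2 and T12 (3.63%) in the syngeneic library. Interferon-induced genes were among the genes that led T4, such as Irf7, and T12, such as Ifit3, over the other syngeneic T cells, so part of the syngeneic CD4 T and CD8 T cells formed clusters led by such genes. Regulatory T cells were T9 and T5, and B cells were clusters 9 and 2. Such a cluster may reflect its library as well as its cell type, and genes within a class are compared with that limit. T cell subclusters with no narrower name were left out of the 4 classes. Of these, T7, led by genes such as Ccl4, Nr4a1 and Cd69, held 12 allogeneic and 301 syngeneic cells. T10, with Ccl5, Xcl1 and Lag3 among its leading genes, held 0 and 147. Mostly syngeneic cells were thus left out there, and the effect on the ratios was not tested. The median log2 ratio over all measured genes, allogeneic over syngeneic, was 0.15 in CD4 T cells, 0.09 in CD8 T cells, 0.18 in regulatory T cells and 0.13 in B cells, so values near these show no difference from the bulk of genes.

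Genes induced by type I interferon, the antiviral cytokine family, had higher CPM (UMI counts scaled to a common total per class) in the allogeneic library in all 4 classes. All measured members were higher in CD4 T cells (31 of 31), regulatory T cells (29 of 29) and B cells (30 of 30), and 30 of 31 in CD8 T cells, where the exception was Ly6e at 119.7 against 125.0 CPM. The median member was 3.31-fold higher in CD4 T cells (log2 1.73, 1.55 to 1.81), 4.45-fold in CD8 T cells (log2 2.15, 1.94 to 2.21), 2.75-fold in regulatory T cells (log2 1.46, 1.33 to 1.69) and 5.88-fold in B cells (log2 2.56, 2.21 to 2.71). Each of these medians lay at percentile 100 of 10000 matched random lists, as a description of these libraries. Irf7, the transcription factor that amplifies interferon production, reached 536 against 45.0 CPM in B cells (log2 3.57, 3.33 to 3.82). Ifi203, an interferon-inducible DNA-binding protein, was 1.71-fold higher in CD4 T, 1.63-fold in CD8 T, 2.13-fold in regulatory T and 3.15-fold in B cells. Ifi27l2a, an abundant member, differed less than the median member, with log2 ratios of 0.46, 0.55, 0.13 and 0.85, and its order in regulatory T cells turned under median-of-ratios scaling (log2 -0.050), with doublets kept (log2 -0.42), at other random starts (set 2, log2 -0.42) and with the 5% highest doublet scores removed (log2 -0.26). In B cells the median was 1.77 among members with at least 100 UMIs.

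**Figure D3:**
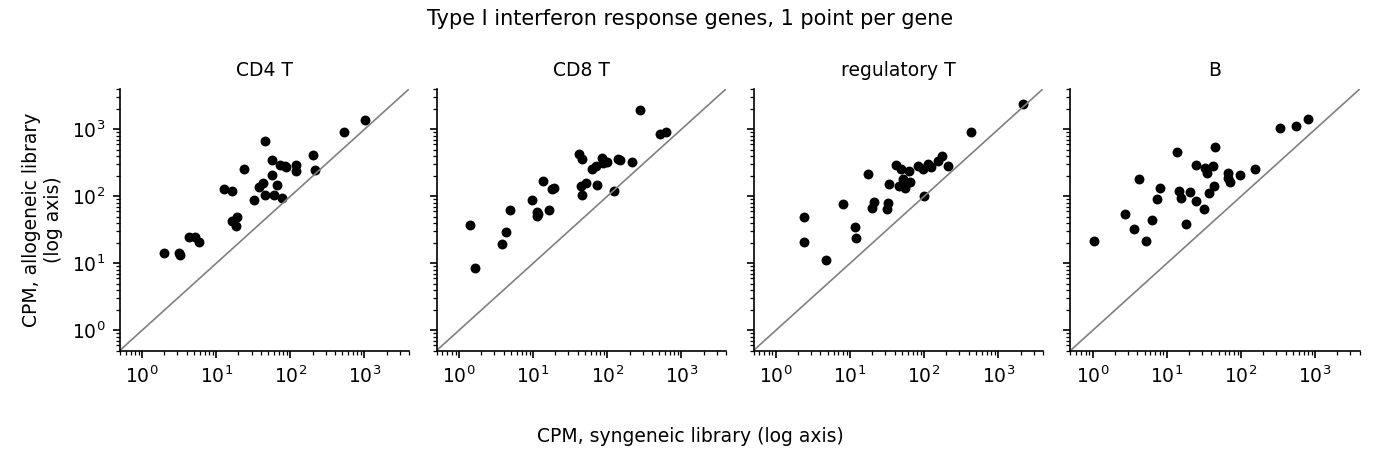
CPM of each measured type I interferon response gene in the allogeneic library (vertical log axis) against the syngeneic library (horizontal log axis) in 4 cell classes, with the line of equal CPM. Nearly all points lie above the line, with 30 of 31 genes above it in CD8 T cells and all measured genes in the other classes.

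The interferon-gamma list, which holds guanylate-binding proteins, immunity-related GTPases and immunoproteasome subunits, stood at percentile 100 in each class with smaller medians. Its log2 medians were 0.70 in CD4 T (16 of 20 members higher), 1.0 in CD8 T (19 of 21), 0.76 in regulatory T (14 of 20) and 1.06 in B cells (15 of 19), and the regulatory T median was -0.0042 among cells of at least 3447 UMIs. Gbp4, a guanylate-binding protein, was 1.55-fold higher in CD4 T and 2.23-fold in CD8 T cells, and Irgm1, an immunity-related GTPase, was 4.74-fold higher in B cells. Its members did not move together: Psmb9, an immunoproteasome subunit, had lower CPM in allogeneic CD4 T (log2 -0.47), CD8 T (log2 -0.36) and regulatory T cells (log2 -0.76). MHC class I presentation genes had log2 medians of 0.65, 0.54, 0.80 and 0.61 in CD4 T, CD8 T, regulatory T and B cells, at percentiles of 99.8 or above. H2-Q4, a non-classical class I gene, was 2.83-fold higher in CD4 T, 2.81-fold in CD8 T and 3.32-fold in regulatory T cells, and the classical gene H2-D1 was 1.42-fold, 1.40-fold and 1.61-fold higher. Class I genes are near-identical copies of each other and the mm10 reference carries the C57BL/6 alleles, so counts of single members are uncertain.

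CD4 T cells of the allogeneic library had higher CPM of NF-kB and TNF genes and of checkpoint receptors. Ctla4, an inhibitory receptor induced on activated T cells, reached 22.9 against 1.53 CPM (15-fold, log2 3.91, 3.11 to 4.78), and Cd200, an inhibitory ligand, 65.6 against 8.98 CPM (7.30-fold). Cd69, an early activation antigen that retains lymphocytes in lymph nodes and is also induced by interferon, was 6.22-fold higher at 233 against 37.4 CPM. Subcluster T7, which had Cd69, Egr1 and Nfkbid among its leading genes, was outside this class, with 301 syngeneic and 12 allogeneic cells. Ratios of activation, NF-kB and immediate early genes carry that limit. The growth factor gene Il2 was 2.85-fold higher, and the interleukin-7 receptor gene Il7r was 2.46-fold higher. Checkpoint receptors as a list had a log2 median of 1.82 with 5 of 6 members higher, at percentile 100, and of 0.50 with doublets kept, 0.37 at other random starts (set 2) and 0.77 with members of at least 100 UMIs. With doublets kept and at those starts, where few syngeneic cells were named regulatory T, the log2 ratio of Ctla4 was 1.12 and 1.25 and that of Cd200 was 1.51 and 1.12. The NF-kB and TNF list had a log2 median of 0.58 with 10 of 13 members higher, at percentile 99.2, led by its inhibitor Nfkbia at 950.5 against 209 CPM. Bbc3, a p53 target that promotes cell death, was 11.7-fold higher, although its list had a median of 0.27 with 4 of 7 members higher. Cd40lg, the helper ligand for B cells, went the other way at 34.4 against 65.2 CPM, and the T cell activation list as a whole had a log2 median of 0.22 at percentile 71.9, which turned to -0.92 with doublets kept, -0.81 at other random starts (set 2) and -0.20 with free RNA subtracted. Free RNA was estimated for the allogeneic library and subtracted from its sums only, here and below, which lowers ratios of genes that the syngeneic library also carries as background. The lowest ratios belonged to Gimap7, a GTPase of lymphocytes (33.5 against 156 CPM), Lgals1, which encodes galectin-1 (42.2 against 169 CPM), Id3, an inhibitor of E-protein transcription factors (17.0 against 64.1 CPM), and the cytoskeletal genes Lcp1 (119.7 against 366 CPM) and Tmsb4x (5141 against 15450.4 CPM). The highest ratios belonged mostly to haemoglobin and neutrophil genes, among them Hbb-bs at 2458 against 27.0 CPM and S100a8 at 633 against 15.8 CPM. Saa3 stood at 107 CPM against 0 UMIs, which is 420.5-fold higher when computed against a floor of 3 UMIs over the class.

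CD8 T cells of the allogeneic library had higher CPM of Cxcl10, an interferon-induced chemokine that draws activated T cells, at 47.6 against 0.811 CPM (58.6-fold, log2 5.87, 4.96 to 6.93). Cxcl10 was also among the leading genes of the monocyte cluster in the syngeneic library. With an estimated 9.95% of free RNA in allogeneic CD8 T cells, background from other cells is not excluded for this value. Cd69 stood at 205 against 47.6 CPM. Lag3, an inhibitory receptor for MHC class II, stood at 16.2 against 2.06 CPM (log2 2.97, 2.17 to 3.78). The log2 ratio of Lag3 was 1.20 with doublets kept and 1.31 with each library clustered alone. Subcluster T10, with Ccl5, Xcl1 and Lag3 among its leading genes, was outside this class, with 147 syngeneic and 0 allogeneic cells. Its Cd8 level was 0.829 of the highest cluster, and its Cd4 level of 0.159 kept it from the CD8 name. Ratios of Lag3, Xcl1 and the checkpoint and cytotoxic lists carry that limit, and its effect was not tested. Genes of killing differed little: the cytotoxic and effector list had a log2 median of 0.19 with 11 of 18 members higher, at percentile 87.7. Nkg7, a cytotoxic granule protein that also leads these clusters, had 989.7 against 951 CPM, and the granule protease gene Ctsw was 1.22-fold higher. Xcl1, a chemokine for cross-presenting dendritic cells, was lower at 2.24 against 14.8 CPM. Checkpoint receptors had a log2 median of 1.28 with 5 of 7 members higher, at percentile 99.9. When free RNA was subtracted, this median was 0.087 and the order of the member Cd200 turned (log2 -0.87), and with members of at least 100 UMIs the median was 0.35. Oxct1, an enzyme of ketone body use, had 16.8 against 65.5 CPM, the adhesion molecule gene Icam2 had 20.7 against 63.9 CPM, and Id3 had 22.4 against 69.1 CPM. Trnp1 stood at 57.1 against 0.590 CPM (96.7-fold), the highest ratio outside haemoglobin, neutrophil and acute-phase genes.

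Regulatory T cells of the allogeneic library had lower CPM of cytotoxic and effector genes and higher CPM of immediate early genes. Lgals1 had 60.4 against 459.6 CPM (log2 -2.93, -3.40 to -2.49), the calcium-binding protein gene S100a4 had 22.5 against 147 CPM, the chemokine gene Ccl5 had 19.7 against 80.6 CPM, and Ly6c2 had 9.83 against 53.3 CPM. Ccl5 and Ly6c2 were also lower in allogeneic B cells, at 25.1 against 56.2 CPM and 42.6 against 103 CPM, so their regulatory T values are not told from background. Nkg7 had 63.2 against 167 CPM. It too was lower in allogeneic B cells (log2 -0.98, -1.82 to -0.24), so the same limit applies to it. The cytotoxic and effector list had a log2 median of -1.22 with 8 of 10 members lower, at percentile 0. In B cells the median of this list was -0.49 with 6 of 10 members lower, so part of its drop is not told from background either. Markers of the class differed too: Foxp3, its defining transcription factor, had 206 against 79.4 CPM and Ctla4 388 against 48.1 CPM (log2 3.01, 2.70 to 3.33, and 0.46 with doublets kept and 0.42 at other random starts, set 2), whereas Ikzf2 had 368 against 412 CPM. After thinning to 1000 UMIs, Foxp3 was seen in 17.3% of allogeneic and 7.71% of syngeneic cells and Ctla4 in 30.5% and 4.31% (unthinned 43.4% and 30.2%, 62.9% and 20.4%). The class was thus not shown to be equally pure in both libraries, and the lower cytotoxic values carry that limit. Ccr7, a receptor for homing to lymph nodes, was 2.12-fold higher, and Klf2, a transcription factor of lymphocyte recirculation, 1.90-fold higher. Cd69 was 7.22-fold higher at 475 against 65.8 CPM, and Il2rb, a receptor chain for interleukin-2, was 1.96-fold higher. Immediate early genes had a log2 median of 1.14 with 11 of 13 members higher, at percentile 100, with Junb at 635 against 221 CPM and Nfkbia at 1179.8 against 349 CPM. With each library clustered alone, the order of S100a4 turned (log2 0.85) and the log2 ratio of Lgals1 was -1.33, and the cytotoxic median was 0.10 when members with at least 5 UMIs were counted.

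B cells of the allogeneic library had lower CPM of B cell activation, heat shock and glycolysis genes. Fcer2a, which encodes the low-affinity IgE receptor CD23 of follicular B cells, had 53.9 against 536 CPM (log2 -3.31, -3.78 to -2.88), and Cr2, the complement receptor CD21, had 33.8 against 216 CPM. Both are among the markers from which B cell clusters were named, and Fcer2a led cluster 2. Ccr6, a chemokine receptor, had 22.6 against 199 CPM, Il4i1, an amino acid oxidase induced by interleukin-4, had 17.5 against 390.2 CPM, and Pcp4, a calmodulin-binding peptide, had 2.51 against 59.7 CPM. The activation antigen gene Cd83 had 127 against 413 CPM and the cyclin gene Ccnd2 had 62.6 against 278 CPM. The B cell activation and germinal centre list had a log2 median of -0.79 with 10 of 12 members lower, at percentile 0, and of -0.25 with each library clustered alone. Heat shock genes had a log2 median of -1.02 with 7 of 8 members lower, led by Hsp90ab1 at 357 against 1150.5 CPM, and glycolysis genes one of -0.60 with 10 of 12 lower, including the lactate dehydrogenase gene Ldha at 164 against 353 CPM. Outside the interferon genes, Dusp1, a phosphatase of stress kinases, was 39.6-fold higher at 142 against 3.58 CPM, Cd200 was 3.89-fold higher and Ccr7 2.19-fold higher. Ifit3b, at 180.4 against 4.21 CPM, is nearly identical to Ifit3, so its own count is uncertain. MHC class II genes had a log2 median of -0.11 with 6 of 11 lower, and the invariant chain gene Cd74 had 23094 against 22922 CPM.

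**Figure D4:**
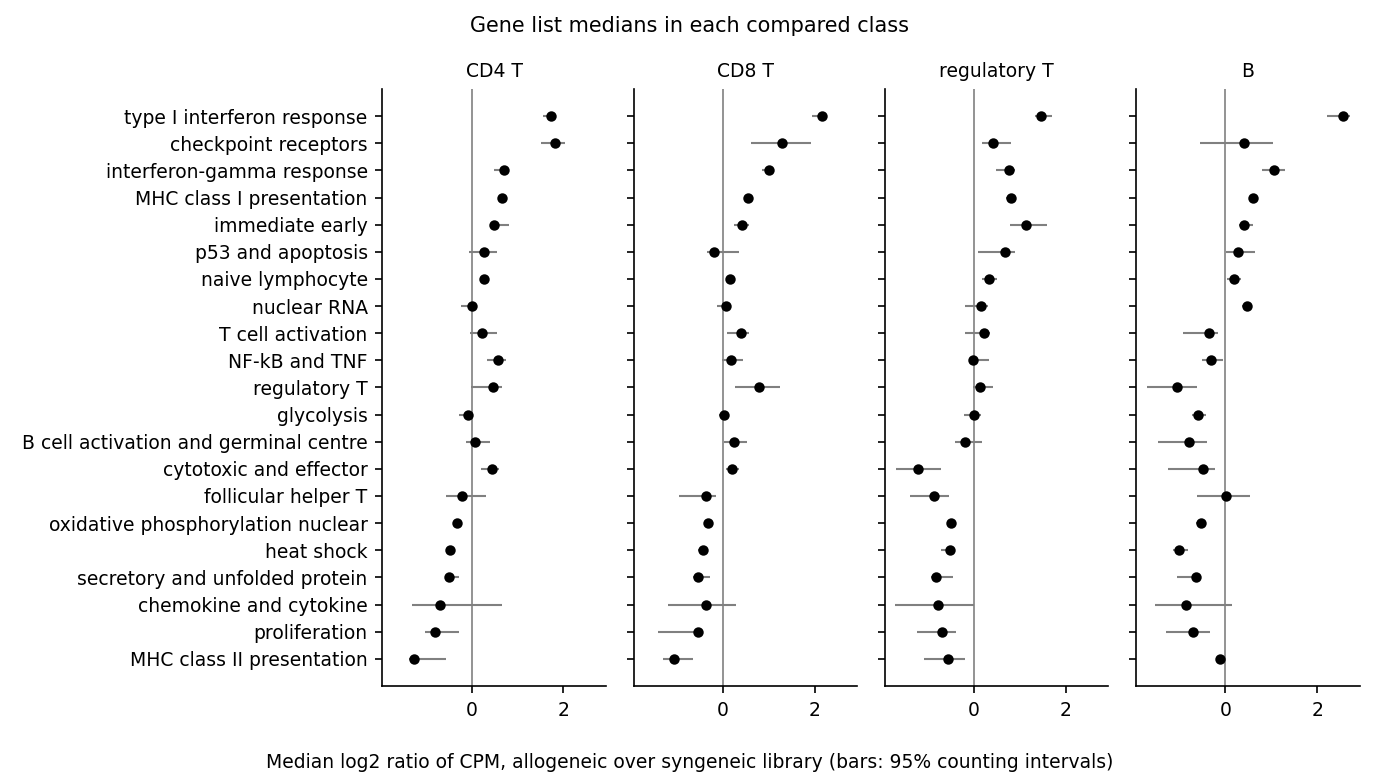
Median log2 ratio of CPM, allogeneic over syngeneic library, of each gene list (rows) in 4 cell classes (panels), with 95% counting intervals as bars. Type I interferon response genes have the highest median in CD8 T (2.15), regulatory T (1.46) and B cells (2.56), and checkpoint receptors in CD4 T cells (1.82 against 1.73).

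The remaining lists are given as log2 medians in the order CD4 T, CD8 T, regulatory T and B cells. Proliferation genes had medians of -0.79, -0.55, -0.70 and -0.70, at percentiles of 1.66 or below, and of -0.20 in CD4 T and -0.21 in B cells among members with at least 100 UMIs. Genes of secretion and the unfolded protein response had -0.49, -0.54, -0.83 and -0.63, although Herpud1 was 2.31-fold higher in B cells. Nuclear-encoded oxidative phosphorylation genes had -0.33, -0.33, -0.50 and -0.53, with 0 of 21 members higher except in CD8 T cells, where 1 of 21 was. Heat shock genes had -0.47, -0.42 and -0.52 in the T cell classes. MHC class II genes had -1.25, -1.07 and -0.58 in the T cell classes, with Cd74 at 144 against 363 CPM in CD4 T cells, although T cells make little of it. These medians were -2.38, -3.35 and -2.18 with free RNA subtracted from the allogeneic sums only, so the further drop is not read as expression, and the regulatory T median was -0.12 when members with at least 5 UMIs were counted. Immediate early genes had 0.50, 0.42 and 0.41 in CD4 T, CD8 T and B cells, and the CD8 T median was -0.086 among members with at least 100 UMIs. Naive lymphocyte genes had 0.28, 0.16, 0.33 and 0.19. NF-kB and TNF genes had 0.17, -0.02 and -0.31 in CD8 T, regulatory T and B cells, and T cell activation genes had 0.39, 0.22 and -0.36 there. Checkpoint receptors had 0.42 in regulatory T and 0.39 in B cells, and cytotoxic and effector genes had 0.44 in CD4 T cells and -0.49 in B cells. Regulatory T genes had 0.47, 0.79, 0.12 and -1.06, follicular helper T genes -0.22, -0.36, -0.88 and 0.01, and B cell activation and germinal centre genes 0.07, 0.24 and -0.19 in the T cell classes. The p53 and apoptosis list had -0.20, 0.67 and 0.28 in CD8 T, regulatory T and B cells. Glycolysis genes had -0.08, 0.02 and 0.01 in the T cell classes. Chemokine and cytokine genes had -0.68, -0.36, -0.79 and -0.86 from 3 to 8 measured members, and nuclear RNA had -0.0023, 0.06, 0.16 and 0.47. Many of these medians changed sign under some alternative. Regulatory T genes turned to -1.31 in CD4 T and -1.03 in regulatory T cells at other random starts (set 2) and to -0.056 in CD8 T cells with free RNA subtracted. Chemokine and cytokine genes turned to 1.51 in CD4 T, 0.36 in CD8 T and 0.39 in regulatory T cells when members with at least 5 UMIs were counted. Follicular helper T genes turned to 1.32 in regulatory T cells with each library clustered alone and to -0.74 in B cells with members of at least 5 UMIs. In regulatory T cells, B cell activation genes turned to 0.60 and NF-kB and TNF genes to 0.62 among cells of at least 3447 UMIs, and glycolysis genes to -0.74 at other random starts (set 2). With free RNA subtracted, cytotoxic genes turned to -0.11 in CD4 T cells, and T cell activation genes to -0.10 and NF-kB and TNF genes to -0.11 in CD8 T cells. Of the immunoglobulin constant list only Jchain was measured, and the other members were not analysed here.

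Summed over all kept cells, type I interferon genes had higher CPM and proliferation genes lower CPM in the allogeneic library. Saa3, an acute-phase protein, stood at 1109 against 0.0431 CPM, Ifitm6 at 629 against 1.08 CPM, the chitinase-like gene Chil3 at 233 against 0.172 CPM and Il1b, the inflammatory cytokine interleukin-1 beta, at 56.2 against 1.74 CPM. Jchain, the joining chain of secreted antibodies, had 16.3 against 96.5 CPM, the dendritic cell gene Fscn1 had 13.8 against 59.7 CPM, the dendritic cell chemokine gene Ccl22 had 5.40 against 25.8 CPM, and Birc5, a gene of mitosis, had 12.5 against 51.2 CPM. All 20 proliferation genes were lower, with a log2 median of -1.54 (-1.64 to -1.39), and the type I interferon median was 1.79 (1.71 to 1.86) with 32 of 32 members higher. Pdcd1, which encodes the inhibitory receptor PD-1, was 3.33-fold higher at 29.2 against 8.76 CPM, and Ctla4 was 7.07-fold higher at 68.7 against 9.71 CPM. These sums mix cell makeup with expression. With classes reweighted to equal shares the proliferation median was -0.46.

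Shares of cells with a UMI were compared after each cell was thinned to 1000 UMIs, which left out 300 allogeneic cells and 0 syngeneic cells. Ifit3, an interferon-induced antiviral gene, was seen in 19.3% of allogeneic and 2.08% of syngeneic CD4 T cells, 34.9% and 3.34% of CD8 T cells, 16.8% and 1.36% of regulatory T cells, and 33.9% and 1.33% of B cells. Without thinning these shares were 44.4% and 8.28%, 71.0% and 14.6%, 36.2% and 7.94%, and 52.5% and 4.62%. Thinned erythroid cells, which should lack the gene, showed it in 0 of 69 allogeneic cells (interval up to 5.21%) and 0 of 6 syngeneic cells, the former at a median depth of 9606 UMIs before thinning, against 3312 for CD4 T, 4261.5 for CD8 T, 2986 for regulatory T and 2328 for B cells. Without thinning, 6 of 69 allogeneic erythroid cells showed it (8.70%, 3.26 to 18.0%) and 0 of 6 syngeneic ones. In B cells Cd83 was seen in 8.79% of allogeneic and 29.4% of syngeneic cells (unthinned 21.6% and 67.5%), against 0.765% and 1.25% of CD8 T cells, and B and CD8 T cells had median depths of 2328 and 4261.5 UMIs in the allogeneic and 4191 and 5335.5 UMIs in the syngeneic library. S100a8 was seen in 44.6% of allogeneic and 0.392% of syngeneic CD4 T cells, and Hbb-bs in 90.8% and 2.32% (unthinned 86.0% and 1.61%, 100% and 11.5%). T cells do not express these genes, so their shares are read as background.

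The check genes gave no sign of mixed sexes. Xist, expressed in female cells, had 0.790 and 0.323 CPM and Tsix 1.18 and 1.10 CPM in the allogeneic and syngeneic libraries, while the Y-linked genes Ddx3y (68.0 and 60.1 CPM), Eif2s3y (101 and 78.9 CPM), Uty (22.8 and 13.8 CPM) and Kdm5d (16.6 and 19.6 CPM) were present in both. Of the strain check genes, Gbp2b had 41.1 and 38.9 CPM, Nnt 12.2 and 11.2 CPM, Ly6c2 196 and 415 CPM and Ly6a, also an interferon-induced gene, 776 and 177 CPM, and H2-Ea-ps and Ighg2c were not analysed here.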

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

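The tests in this part were written before their results were seen, on patterns that had already been seen. Erythroid and neutrophil RNA appeared in allogeneic barcodes that no comparison uses. Of the 545285 UMIs in the 1071 allogeneic barcodes with fewer than 200 genes, 64.4% (64.2 to 64.5%) were haemoglobin and 0.333% (0.318 to 0.348%) were S100a8 and S100a9, far above the 0.000550% that a count of 0 allows. In the 942 of them with at most 50% haemoglobin, 4.83% of 184696 UMIs were haemoglobin. Most haemoglobin UMIs thus lay in the barcodes over 50% haemoglobin, and the 64.4% is not the makeup of free RNA. Haemoglobin and neutrophil genes also led the allogeneic ratios of T and B cells. Doublets with red cells were argued against by the spread of haemoglobin over cells. The tenth of cells richest in haemoglobin held at most 35.8% of a class's haemoglobin UMIs, in CD8 T cells. Every cell of the 4 classes had some. The test used haemoglobin alone, so it cannot decide on doublets with neutrophils. Free RNA from 1 pool may account for the haemoglobin and neutrophil UMIs of the 4 classes. S100a8 and S100a9 over haemoglobin lay between 0.189 in CD8 T and 0.258 in CD4 T cells, a 1.36-fold range. Their intervals, 0.180 to 0.200 and 0.247 to 0.271, did not overlap. The ratio was 0.185 in the 942 barcodes whose UMIs were at most 50% haemoglobin. Over all 1071 barcodes, 1814 S100a8 and S100a9 UMIs stood against 350996 haemoglobin UMIs, so the 0.185 rests on leaving out the barcodes over 50% haemoglobin. No biological explanation was tested, and blood in the allogeneic lymph node stays open as the source of the pool.

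Several lists had medians of opposite sign in 2 classes of the same libraries, and none of these differences was tested. The B cell activation and germinal centre list differed by 1.03 on the log2 scale between CD8 T cells (0.24) and B cells (-0.79). NF-kB and TNF genes differed by 0.90 between CD4 T cells (0.58) and B cells (-0.31), and T cell activation genes by 0.75 between CD8 T cells (0.39) and B cells (-0.36). Cytotoxic and effector genes differed by 1.66 between CD4 T cells (0.44) and regulatory T cells (-1.22). The regulatory T list differed by 1.85 between CD8 T cells (0.79) and B cells (-1.06). After subtraction of free RNA from the allogeneic sums only, the CD8 T medians of T cell activation (-0.10) and regulatory T genes (-0.06) and the CD4 T median of cytotoxic genes (-0.11) no longer had the opposite sign.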

How the results depend on the processing

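Type I interferon medians stayed above 0 in every class under the alternatives that gave a value, whose ranges were 1.51 to 1.73 in CD4 T, 2.01 to 2.15 in CD8 T, 1.28 to 1.59 in regulatory T and 1.77 to 2.65 in B cells. In a separate test on cells of at least 3447 UMIs that kept the main class names they were 1.496, 2.19, 1.55 and 1.65. Of 288 class shares under alternatives, 188 stayed within their main intervals and 100 moved. Of 1065 list medians under alternatives, 879 stayed within their intervals, 172 moved and 14 changed sign where the main interval excluded 0, and of 1781 ratios of named genes 1476 stayed, 289 moved and 16 changed sign in this way. A further 65 medians and 15 ratios changed sign where the main interval held 0 and are counted above as stayed or moved. Shares of cells with a UMI moved in 87 of 96 cases. The cause was not tested for any change below except where named. Alternatives that clustered again needed 20 cells in each library for class expression, not 100. With the stricter filter, B and regulatory T cells had too few, as had B cells among deep cells alone. Regulatory T ratios rest on 47 syngeneic cells with doublets kept and at other random starts (set 2). They rest on 59 syngeneic cells with the 5% highest doublet scores removed and on 70 allogeneic cells among deep cells. No paired analysis was possible because each group had 1 library. Depth limits ratios of low genes: 3 UMIs are 4.21 CPM in allogeneic regulatory T cells and 0.221 CPM in syngeneic CD8 T cells.

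Shares below are percentages of cells, other values log2 ratios. Leiden resolution 0.5 gave syngeneic shares of 31.5 (CD8 T) and 6.52 (regulatory T). Resolution 2 gave CD4 T 41.5 (allogeneic) and 37.4 (syngeneic), CD8 T 27.6 (syngeneic) and regulatory T 0.430 and 0.691. At least 500 genes and at most 5% mitochondrial UMIs gave allogeneic B 0.352, CD4 T 36.6, CD8 T 23.3 and regulatory T 1.12, and syngeneic regulatory T 8.39. Without a cell filter the allogeneic shares were 9.26 (B), 18.5 (CD4 T), 11.3 (CD8 T) and 6.43 (regulatory T), lower because added barcodes enlarge the total, and syngeneic ones 31.2 (CD8 T) and 0.628 (regulatory T). After thinning to 1000 UMIs, B was 0.782 (allogeneic), CD4 T 0 in both libraries, and CD8 T 0.949 and 27.0, where no cluster was named CD4 T. Doublets kept gave syngeneic CD4 T 37.7, CD8 T 31.7 and regulatory T 0.591, and turned Ccl5 in CD8 T (-0.068), Ifi27l2a (-0.42) and Ly6a (-0.11) in regulatory T, and cytotoxic genes in CD4 T (-0.10). Removing the 5% highest doublet scores gave syngeneic CD8 T 31.1 and regulatory T 0.780, and turned Ccl5 (-0.12) and cytotoxic genes (-0.017) in CD8 T and Ifi27l2a in regulatory T (-0.26). Each library clustered alone gave syngeneic regulatory T 2.85, and turned S100a4 (0.85), chemokine (0.50) and follicular helper genes (1.32) in regulatory T. Cells of at least 3447 UMIs alone gave allogeneic B 0.231, CD8 T 36.6 and regulatory T 8.08, syngeneic regulatory T 3.76 and a CD4 T type I interferon median of 1.51. There, in regulatory T, Igtp (-0.0042), interferon-gamma genes (-0.0042), naive genes (-0.028) and follicular helper genes (0.15) turned. Other random starts gave syngeneic CD8 T 31.8 (sets 1 and 2) and 31.3 (set 3), CD4 T 37.7 (set 2) and regulatory T 0.591 (set 2) and 6.16 (set 3), and turned Ccl5 in CD8 T (-0.061, -0.060 and -0.085) and, in set 2, Ifi27l2a (-0.42), Igtp (-0.037) and Ly6a (-0.22) in regulatory T. Free RNA subtracted from the allogeneic sums only turned Cd200 (-0.87), S100a9 (-1.72), T cell activation (-0.10) and regulatory T genes (-0.056) in CD8 T, cytotoxic genes in CD4 T (-0.11) and MHC class II genes in B (0.015). Members with at least 100 UMIs gave type I interferon medians of 1.77 (B) and 1.55 (CD4 T) and immediate early -0.086 (CD8 T). Members with at least 5 UMIs gave chemokine 0.39 and cytotoxic 0.10 in regulatory T. Median-of-ratios scaling gave a type I interferon median of 1.28 and Ifi27l2a -0.050 in regulatory T. Over all cells, the type I interferon median was 1.63 in CPM without mitochondrial, ribosomal protein and immunoglobulin genes and 1.97 with classes reweighted.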

Other observations

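The list of further glucocorticoid-linked genes was written before its values were seen. The tests of heat and of handling stress, the part of the UMI minimum test that covers T cell classes alone and the statement on graft type were chosen after results were seen. Genes that glucocorticoid hormones induce stood out in the allogeneic library without being in any fixed list. Fkbp5, a co-chaperone of the glucocorticoid receptor, had 193 against 8.84 CPM in B cells, 172 against 10.1 in CD4 T, 107 against 13.1 in CD8 T and 156 against 16.0 in regulatory T cells. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 17.2-fold higher in B, 5.90-fold in CD4 T, 6.30-fold in CD8 T and 8.75-fold in regulatory T cells. Klf9, a transcription factor, was 7.29-fold to 17.8-fold higher, and Txnip, an inhibitor of thioredoxin and glucose uptake, 3.62-fold to 7.08-fold.

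A wider glucocorticoid response is a candidate explanation of this pattern. The further list had log2 medians of 0.98 in CD4 T, 0.60 in CD8 T, 0.87 in regulatory T and 1.0 in B cells, and its lowest percentile among matched random lists was 99.7. Without Lcn2, a member that neutrophils also make and that was left out after its values were seen, the medians were 0.83, 0.57, 0.86 and 0.99, with a lowest percentile of 99.6. Free RNA supplied at most a median of 19.3% of the excess of the 4 genes, in CD8 T cells. Heat stress was argued against by the heat shock list, whose highest class median was -0.42. Handling stress of the cells stays open: immediate early genes had medians above 0 in all 4 classes, the lowest 0.41 in B cells, but the CD8 T median was -0.086 among members with at least 100 UMIs. Graft type, hormone level at sampling and handling of the animals stay open too, since each group had 1 library.

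The type I interferon pattern was set against free RNA, depth and graft type. Free RNA supplied a median of at most 12.4% of the members' excess, in CD4 T cells. With only cells of at least 3447 UMIs, the list median kept at least 0.867 of its value in the T cell classes, which argues against the UMI minimum of the barcode lists as its cause there. In B cells, where 32 allogeneic cells reach that depth, the median was 1.65 (1.25 to 2.02), 0.645 of its value, and part of the excess could come from the depth gap. Graft type may underlie the pattern and cannot be told apart from any other difference between the libraries, because each group had 1 library.

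Symbols of processed pseudogenes had higher CPM in the allogeneic library in every class, 14 of 14 in CD4 T, 13 of 13 in CD8 T, 11 of 11 in regulatory T and 12 of 12 in B cells, with log2 medians of 2.09, 2.2, 2.2 and 2.04. The ribosomal protein genes, many of them their parents, had medians of -0.24, -0.20, -0.27 and -0.22. Whether the reads of both libraries were trimmed and mapped alike is not given in the sources used here. No explanation of this excess was tested, and a difference in read processing stays open, which would bear on all ratios between the libraries.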
